A study of Homo sapiens with 18 samples.

How the data were processed

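Pools of 125-nt human pri-miRNA substrates were synthesised as DNA, transcribed in vitro and incubated with purified recombinant Microprocessor, per the labels' protocols. A reaction of 10 µl held 40 fmol of substrate and 200 fmol of Microprocessor in buffer with 500 mM NaCl and 2 mM MgCl2, and ran at 37 °C for 1 h. Product fragments were ligated to adapters on both ends, whereas input RNA was reverse-transcribed with its own primers, per the labels' protocols, so that ligation preferences act on products and not on input. The 18 libraries, 8 of input and 10 of products, were grouped by their labels into 5 biological replicates. Whether these are separate transcriptions or separate reactions is not given in the sources used here. The p-values of the edgeR and DESeq2 fits and of exact tests over replicates measure the spread between these samples, which may be technical. The other p-values come from tests over pri-miRNAs and do not measure that spread.

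The deposited input values are raw counts of reads per pri-miRNA in each library. The deposited product values are estimated counts per fragment, that is per pri-miRNA and first and last nucleotide on the substrate, and were not scaled. Product values were not whole (tolerance 0.0010) for 7.39% of the fragments, and 105 pri-miRNAs had over 10% of their reads at such split values. In 25 groups, holding 54 pri-miRNAs, all values were identical. Values of such copies are uncertain, and the share of reads at split values is a lower bound of the share that is not unique, since a shared count can divide evenly. Cutadapt 2.3 and Bowtie2 2.2.4 were used, per the submitters' processing notes; their roles and settings, and the use of the degenerate adapter bases to remove PCR duplicates, are not given in the sources used here. PCR copies are not independent molecules, so intervals and floors cover counting error only.

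Fragments were classed by the substrate ends they keep, with a tolerance of 3 nt. Flanks reach one end of the substrate and were cut before its midpoint, at least 10 nt from that end. Single-arm products reach one end and were cut beyond the midpoint, at least 10 nt inside the other end. Pre-miRNA-like products have both ends at least 10 nt inside and a length of 45 to 90 nt, and short middle products a length of 28 to 44 nt. Of the reads with both ends inside, 0.155% were shorter than 28 nt. Technical replicates were summed within a biological replicate. Their log2 shares correlated with r from 0.979 to 0.994 for products and 0.995 to 0.999 for input, across pri-miRNAs, and all pairs differed by more than sampling noise, with chi-square per degree of freedom from 2.19 to 74.0.

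The processing score is log2 of (pre-miRNA-like reads + 1) as a share of their total, minus log2 of (input reads + 1) as a share of theirs, centred on the median of each replicate and averaged over replicates. It required at least 10 reads in each input library of the replicate, which 57 pri-miRNAs did not reach in any replicate. The floor for 0 reads was 3 counts per replicate. The median number of product reads of all classes per pri-miRNA with input was 11549.5, 965, 900, 4088.5 and 7509.9 in replicates 1 to 5. Precision is the share of pre-miRNA-like reads at the main 5′ or 3′ nucleotide, for pri-miRNAs with at least 100 such reads in every product library of a replicate. The single-arm ratio is log2 of (3′-arm-only reads + 1) over (5′-arm-only reads + 1). Both were tested by two-sided sign-flip permutation over pri-miRNAs (100000 resamples) and, as an exact test, over the 5 replicates. Permutation over pri-miRNAs describes these pools, since pri-miRNAs and paralogs among them are not independent.

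Product counts were rounded to whole numbers and tested against input counts with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, no block, Benjamini-Hochberg adjustment, threshold 0.05), in R 4.3.3 with limma 3.58.1. DESeq2 1.42.0 was the alternative. Standard errors of edgeR log2 changes were taken as the change divided by the square root of its F value. The design asked for the same pri-miRNAs in 3 or more replicates, and the fits on replicates 1, 2 and 5 and on replicates 2, 3 and 4 meet this. A fit on replicates 1 and 2, which hold most of the collection, was added after the data were seen. The replicate numbers pair the samples, because input and products with the same number come from the same substrate pool. The correlation of their deviations from the group means was 0.768, 0.830 and 0.914 in the first fit, 0.769, 0.794 and 0.757 in the second and 0.289 in the fit on replicates 1 and 2.

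The edgeR fits were tested on simulated data with the real library sizes. Simulations without the block used mean shares over all samples and the dispersion (spread beyond counting noise) of the fit without the block. Those with the block used the input composition of each replicate and the dispersion of the fit with the block. Their counts therefore do not show the effect of the block alone. In the fit on replicates 1 and 2, with 1667 pri-miRNAs, 62 of 63 simulated 16-fold changes, 18 of 66 4-fold changes and 1 of 71 2-fold changes were called, with 2 of 1467 unchanged pri-miRNAs. In replicates 1, 2 and 5, with 193 pri-miRNAs, none was called without the block (0 of 23 16-fold changes, dispersion 1.60). In the simulation with the block, 23 of 23 were called (dispersion 0.267). In replicates 2, 3 and 4, with 118 pri-miRNAs, 4 of 8 16-fold changes were called without the block (dispersion 0.893). In the simulation with the block, 6 of 8 were called (dispersion 0.269). The permutation functions were also tested on simulated data. That test led to 1 correction after a first run on the real data: list p-values are now measured around the permutation mean, since replicate membership alone shifts it. The correction brought the adjusted single-arm result of the 14q32 list under the threshold, where it now stands at 0.0201.

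Of 22 lists of pri-miRNAs, 20 had 3 or more members with a score and 19 had 3 or more for each of the other measures. The differences of list medians were tested by two-sided permutation of membership (100000 resamples) among pri-miRNAs measured in the same replicates, with Benjamini-Hochberg adjustment over lists. Intervals of list differences are 95% bootstrap intervals over members (2000 draws). The list of late-numbered pri-miRNAs holds all with a number of 3000 or above. Alternatives used 10000 resamples. Tests within single replicates and the count of joined middle and flank products (at least 100 flank reads, 100 shuffles, Fisher's exact test over lists) were added after the data were seen. Hairpin positions and host genes come from GENCODE 29 on GRCh38, which holds a hairpin for 1876 of the 1881 pri-miRNAs, with a median length of 80 nt. ViennaRNA 2.7.2 gave the folds. Coordinates are those of the annotated hairpin and not of the substrate, and 1 location is not reported here.

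The measures, tests, lists and other settings to be tried were fixed before the data were examined. The same holds for the rule for named pri-miRNAs, which takes the 10 highest and 10 lowest scores among those with at least 100 reads in every input library, the lowest only if called or if their counting interval lay below the median. It also takes the 5 highest and 5 lowest 5′ shares, the 5 with the most even use of a pair of sites, the 5 highest single-arm shares on each arm, up to 4 members of each list with most input reads, and any let-7 or miR-17-92 member. hsa-mir-1302-2 and the pri-miRNAs without a score were named after their values were seen. The other settings tried were other scalings, filters, lengths, pseudocounts and read minimums, all product fragments, single technical replicates, the replicate block, and leaving out each replicate in turn. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.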

Results

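Human primary microRNAs (pri-miRNAs), the hairpin-bearing transcripts from which microRNAs are made, were cut in vitro by purified recombinant Microprocessor, the complex of the RNase III enzyme Drosha and its RNA-binding partner DGCR8. The comparison of products with input asks how well each pri-miRNA is cut and at which nucleotides. The series held 8 libraries of uncut input RNA and 10 libraries of reaction products, from 5 biological replicates of each kind. Every product sample had 2 technical replicates, as did the input of replicates 1, 3 and 5. Input libraries held 1015390 to 4281990 reads and product libraries 444595 to 19904572 reads. Replicates 1 and 2 held nearly the same pri-miRNAs, 1667 of them shared, and replicates 3, 4 and 5 were smaller pools. At least 10 input reads were counted for 1696 pri-miRNAs in replicate 1 and 1757 in replicate 2, and for 149, 174 and 234 in replicates 3, 4 and 5. Of 1881 pri-miRNAs in the tables, 1824 could be scored, 1777 of them in 2 or more replicates and 336 in 3 or more.

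The reads fell on 3 parts of the 125-nt substrates. The 5′ flank, which runs from the first nucleotide to the 5′ cut, held 35.9% ± 5.32 of product reads (SD, n = 5 replicates), and the 3′ flank held 25.5% ± 6.19. Pre-miRNA-like products, of 45 to 90 nt with both ends at least 10 nt inside the substrate, held 13.2% ± 3.68. Shorter middle products of 28 to 44 nt held 19.7% ± 12.3 and differed most between replicates in percentage points, from 6.11% in replicate 5 to 38.02% in replicate 3. The technical replicates of replicate 4 alone held 18.9% and 33.0%. Products cut on the 5′ arm alone held 1.30% ± 1.25 and those cut on the 3′ arm alone 0.900% ± 0.804. None of the 1007867 listed fragments spanned the whole substrate, so uncut RNA was not counted among the products. No reaction without enzyme was analysed here, and no background was subtracted.

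The processing score is the log2 ratio of a pri-miRNA's share of pre-miRNA-like reads to its share of input reads, centred on the median of each replicate. Its quartiles lay at −2.34 and 2.34, a 25.8-fold span, and the 5th and 95th percentiles lay at −4.12 and 4.51. The median SD between replicates was 0.68. With all product fragments in place of the pre-miRNA-like ones, the distance between the quartiles was 2.86 in place of 4.69. Between replicates 1 and 2, which shared 1667 pri-miRNAs, Pearson's r was 0.92 and Spearman's rho 0.92. In these replicates 88.8% of the pri-miRNAs lay on the same side of the median, where chance gives 50%. The other 9 pairs of replicates had r from 0.61 to 0.89 over 42 to 212 shared pri-miRNAs. These correlations run across pri-miRNAs, which are not independent replicates.

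**Figure D1:**
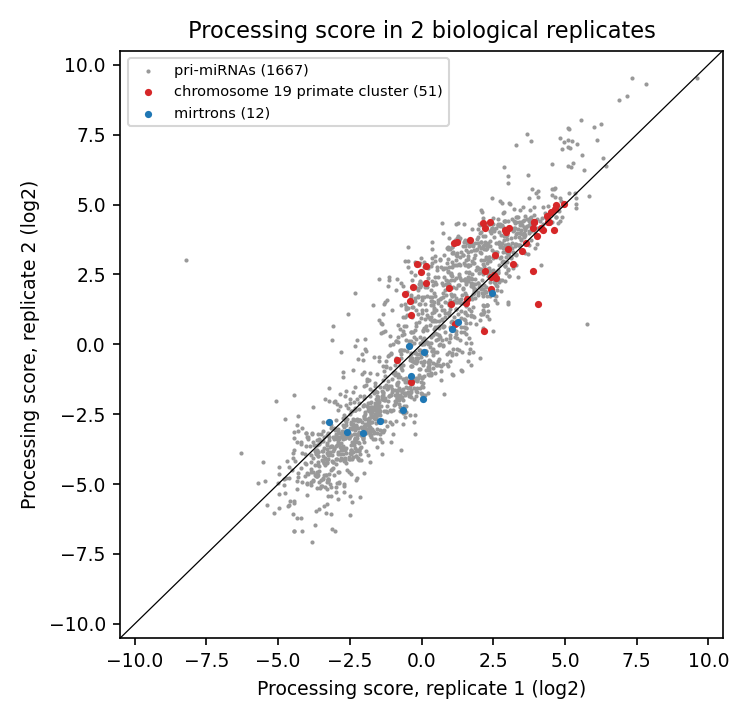
Processing score (log2) of each pri-miRNA in replicate 1 (x axis) against replicate 2 (y axis), with the line of equal values. Grey points are the 1667 pri-miRNAs in both replicates (r = 0.92), red points 51 members of the chromosome 19 list and blue points 12 mirtrons.

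hsa-mir-1269a gave the highest processing score among pri-miRNAs with at least 100 reads in every input library, 7.80 ± 1.31 (SD, n = 2 replicates), which is 222-fold above the median. Its hairpin lies on chromosome 4 at 66276824 to 66276928 (GRCh38) with no gene annotated on that strand. hsa-mir-3923 (chromosome 3, 79507887 to 79507969, also outside genes) followed at 7.47 ± 1.65 (n = 3) and hsa-mir-934 (chromosome X, 136550878 to 136550960, intron of VGLL1) at 6.88 ± 1.25 (n = 2). hsa-mir-149, in an intron of the proteoglycan gene GPC1 (chromosome 2, 240456001 to 240456089), scored 6.41 ± 1.86 (n = 2). The next were hsa-mir-548y at 6.11 ± 1.31, hsa-mir-5590 at 5.96 ± 0.40, hsa-mir-5089 at 5.78 ± 0.79 and hsa-mir-4645 at 5.54 ± 2.45 (n = 2 each). hsa-mir-378a, in an intron of the mitochondrial coactivator gene PPARGC1B (chromosome 5, 149732825 to 149732890), scored 5.38 ± 0.05. hsa-mir-186, in an intron of ZRANB2 (chromosome 1, 71067631 to 71067716), scored 5.31 ± 0.10 (n = 2 each).

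The lowest scores belonged to pri-miRNAs that gave hardly any pre-miRNA-like product. hsa-mir-1302-9 and hsa-mir-1302-11, which have identical values, had 0 such reads in 4 replicates against 589 to 26934 input reads. With 3 counts in place of 0 in each replicate they lay at least 110.6-fold below the median. Their input counts equal those of the near-identical hsa-mir-1302-2, which scored −2.43, so both values are uncertain. The main product of hsa-mir-1302-2 ran from position 13 to 109 (97 nt), above the 90-nt limit of the score. hsa-mir-3658 (chromosome 1, 165907921 to 165907976, untranslated exon of UCK2) scored −6.27 ± 0.29 (n = 3). hsa-mir-4720 scored −5.57 ± 0.27 (n = 2). hsa-mir-3977, hsa-mir-4454, hsa-mir-6723 and hsa-mir-1321 scored −5.46, −5.42, −5.42 and −5.32 (SD 2.29, 0.61, 1.79 and 0.53, n = 2 each). hsa-mir-1244-4 scored −5.34 ± 2.44 (n = 4), with 44.3% of its reads at values split between similar pri-miRNAs. hsa-mir-484, whose hairpin is made by transcription and capping without Microprocessor, scored −5.28 ± 0.39 (n = 4) from an untranslated exon of NDE1 (chromosome 16, 15643294 to 15643372). Counting all product fragments in place of the pre-miRNA-like ones turned 3 of these scores positive, to 1.08 for hsa-mir-1302-9 and hsa-mir-1302-11 and to 1.13 for hsa-mir-4720.

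Across the 1667 pri-miRNAs of replicates 1 and 2, 340 were higher and 696 lower in pre-miRNA-like reads than in input after TMM scaling (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, threshold 0.05). Library totals, which compare shares of reads directly, gave 213 higher and 784 lower. The log2 change was 6.66 ± 0.58 (SE) for hsa-mir-1269a, 5.47 ± 0.73 for hsa-mir-149 and 4.36 ± 0.42 for hsa-mir-378a. It was −6.77 ± 0.70 for hsa-mir-4720. All 4 had an edgeR Benjamini-Hochberg adjusted p of 0.0017. This fit with 2 replicates was chosen after the pools were seen to differ, and its zero depends on the scaling. The median log2 change was −0.90 under TMM, 0.10 under DESeq2 and −1.59 under library totals, and the share of calls that were higher was 32.8%, 51.4% and 21.4%. With all product fragments in place of the pre-miRNA-like ones, edgeR called 527 higher and 558 lower (48.6% higher), and 839 of these calls were shared with the main fit.

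Few pri-miRNAs could be tested in 3 replicates. In replicates 1, 2 and 5, 193 pri-miRNAs were tested and 18 were lower and 0 higher in products (edgeR, Benjamini-Hochberg), with 70 at an unadjusted p under 0.05. DESeq2 called 34 higher and 53 lower. With the replicate as a block, edgeR called 34 higher and 102 lower, and with library totals 7 and 50. The edgeR count was 0 without replicate 1 (27 at an unadjusted p under 0.05), 0 without replicate 2 (14) and 131 without replicate 5. In replicates 2, 3 and 4, 118 pri-miRNAs were tested, of which 19 were higher and 45 lower. DESeq2 called 33 higher and 38 lower, and edgeR with the replicate as a block 31 and 65. The edgeR count was 0 without replicate 4 (43 at an unadjusted p under 0.05), 32 without replicate 2 and 90 without replicate 3.

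The pri-miRNAs of the chromosome 19 list, a primate-specific cluster expressed in placenta, were cut best of the 20 lists tested. The 53 members had a median score of 3.04 against 0.03 for all others, an 8.06-fold difference, and 51 of them lay above the others' median. The difference was 3.01 (95% bootstrap interval over members 2.35 to 3.46) and its permutation p, 1e-05, was the smallest 100000 permutations can give (6.67e-05 after Benjamini-Hochberg adjustment over 20 lists). It was positive in all 4 replicates that held 3 or more members, 2.57, 3.48, 1.84 and 4.84 in replicates 1, 2, 4 and 5. Within single replicates it passed in replicates 1, 2 and 5 (adjusted permutation p = 2e-04 each). In replicate 4, with 3 members, the adjusted permutation p was 0.521. Within replicates 1 and 2, edgeR with Benjamini-Hochberg adjustment called 30 of 51 members higher and 2 lower. Adjusted over the list alone it also called 30 and 2, DESeq2 called 41 and 0, and edgeR with library totals 24 and 2. Of the list, 45 members lie on chromosome 19 and 8, the hsa-mir-513 and hsa-mir-514 hairpins, lie on chromosome X, and without these 8 the difference was 2.94. The identical hsa-mir-514a-2 and hsa-mir-514a-3 scored 4.28 ± 0.32 (n = 3) and hsa-mir-512-1 scored 1.76 ± 0.95 (n = 3). At hsa-mir-512-1, 57.8% of reads were at values split between similar pri-miRNAs, and paralogous hairpins are not independent.

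**Figure D2:**
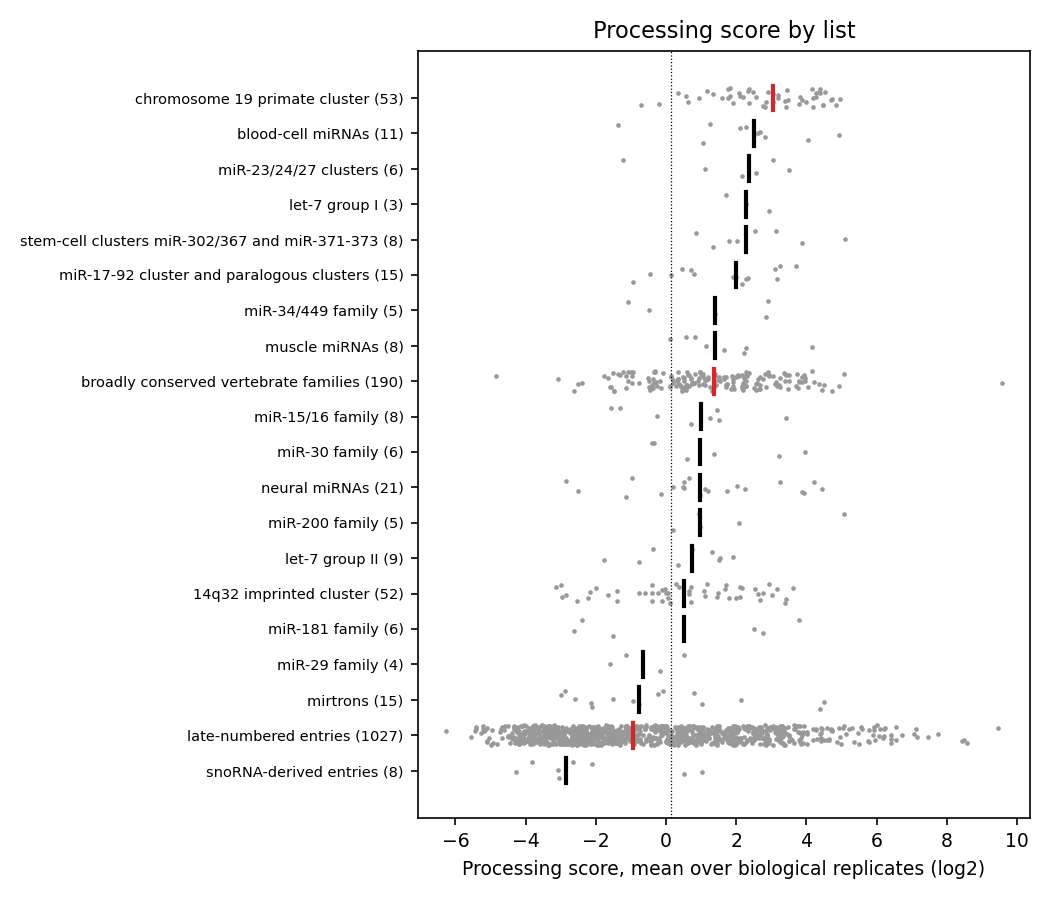
Mean processing score over replicates (log2, x axis) of the members of each list (y axis, number measured in brackets), with one point per pri-miRNA and a bar at the list median. Red bars mark the 3 lists that passed the adjusted test, at medians of 3.04, 1.36 and −0.94; the dotted line is the median of all pri-miRNAs, 0.15.

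Members of broadly conserved vertebrate families were cut better than the rest, with a median of 1.36 against −0.12 (190 members, 149 above the others' median). The difference of 1.48 (95% bootstrap interval 1.09 to 1.83) had an adjusted permutation p of 6.67e-05 and was positive in 5 of 5 replicates. Within single replicates it passed in replicates 1 and 2 (adjusted permutation p = 0.0016 and 2e-04), and in the others, with 6 or 7 members, the adjusted permutation p was 0.274 to 0.621. hsa-mir-219a-1, of a family abundant in brain, scored 4.21 ± 0.85 (n = 4) and hsa-mir-27b 3.50 ± 0.21 (n = 3). Also in this list, hsa-let-7d scored 0.74 ± 1.78 (n = 4) and hsa-mir-190b 0.60 ± 0.07 (n = 3). In replicates 1 and 2, edgeR with Benjamini-Hochberg adjustment called 48 of 186 higher and 25 lower, or 41 and 21 adjusted over the list alone. DESeq2 called 95 and 10, and library totals turned the split to 27 and 39. The pri-miRNAs outside this list included late-numbered ones, which are described next. All pri-miRNAs that were not late-numbered had a median of 1.22, close to the 1.36 of the conserved list. Conserved members were not tested against the others among these, so this difference and the next are not separate results.

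Pri-miRNAs numbered 3000 or above, which were catalogued late, were cut less well. Their median score was −0.94 against 1.22 for all others (1027 members, 727 below the others' median). The difference of −2.16 (95% bootstrap interval −2.43 to −1.81) had an adjusted permutation p of 6.67e-05. Examples are hsa-mir-4280 at −3.38 ± 0.76, hsa-mir-4251 at −2.41 ± 0.83, hsa-mir-6073 at −2.20 ± 0.84 and hsa-mir-4288 at −0.43 ± 0.09 (n = 3 each). The difference was −1.46, −3.10 and −3.54 in replicates 1, 2 and 5. It was 0.40 and 0.88 in the small pools of replicates 3 and 4, with adjusted permutation p of 0.621 and 0.232 in tests added after the result was seen. The 4 highest-scoring members named above, hsa-mir-3923, hsa-mir-5590, hsa-mir-5089 and hsa-mir-4645, are also of this list. In replicates 1 and 2, edgeR with Benjamini-Hochberg adjustment called 133 of 928 higher and 499 lower, or 137 and 503 adjusted over the list alone, DESeq2 242 and 423, and library totals 78 and 545.

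Hairpins that reach the cell's microRNA pool without Microprocessor had lower medians that did not pass the list test. The 15 mirtrons, which are excised by splicing, had a median of −0.76 against 0.16 (adjusted permutation p = 0.305), with 5 of 15 above the others' median and a 95% bootstrap interval of the difference from −2.26 to 0.64. For the mirtrons a difference of 0.73 was expected from replicate membership, and the permutation tested the −1.65 beyond it. Among them hsa-mir-1238 scored −3.00 ± 0.32, hsa-mir-1226 −2.10 ± 0.93 and hsa-mir-3940 −1.50 ± 1.19 (n = 2 each). In replicates 1 and 2, edgeR with Benjamini-Hochberg adjustment called 6 of 12 mirtrons lower and 0 higher, also adjusted over the list alone, DESeq2 4 lower and 1 higher, and library totals gave 7 lower and 0 higher. The 8 hairpins derived from small nucleolar RNAs had a median of −2.85 against 0.16 (adjusted permutation p = 0.268), with 2 of 8 above the others' median and an interval from −3.96 to 0.35. For these hairpins −0.49 was expected from replicate membership and −2.52 lay beyond it. Among them were hsa-mir-3651 at −3.81 ± 0.63, hsa-mir-1248 at −3.07 ± 0.59, hsa-mir-3607 at −3.06 ± 1.32 and hsa-mir-1291 at −2.65 ± 0.42 (n = 3 each). Of 5 tested, edgeR called 3 lower and 0 higher, the same numbers adjusted over the list alone, under DESeq2 and with library totals. Among all 1667 pri-miRNAs of the edgeR fit, 696 were called lower and 340 higher, so lower calls were common in general. The counts of calls in these lists were not tested against that share. The capped hairpins hsa-mir-320a (−3.83 ± 1.502, n = 3) and hsa-mir-484 were too few for a test. hsa-mir-451a, which is matured by Argonaute 2 in place of Dicer after Microprocessor cleavage, scored 1.06 ± 0.10 (n = 2). The score leaves out short middle products, so this value does not show how well hsa-mir-451a was cut to a product of that class.

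The let-7 family, whose members repress growth genes, spread widely. The 3 group I precursors scored 2.92 ± 0.92 (hsa-let-7e), 2.29 ± 1.02 (hsa-let-7a-2) and 1.70 ± 0.10 (hsa-let-7c, n = 2 each), all above the median, with an adjusted permutation p of 0.591 for the list. The 9 group II precursors, whose Microprocessor product has a shorter 3′ overhang, had a median of 0.74 (adjusted permutation p = 0.656). They ran from hsa-let-7i at −1.78 ± 0.35 through hsa-let-7f-1 at −0.77 ± 0.10, hsa-let-7a-3 at −0.36 ± 0.03, hsa-let-7b at 0.35 ± 0.21 and hsa-let-7g at 1.32 ± 0.26 to hsa-mir-98 at 1.92 ± 0.86 (n = 2 each). For hsa-let-7a-1 and hsa-let-7f-2 the scores, 1.55 and 1.51, were smaller than their SDs of 2.196 and 2.03 (n = 2 each). edgeR with Benjamini-Hochberg adjustment called 1 of 3 group I members higher and 2 of 8 group II members lower in replicates 1 and 2, the same numbers adjusted over the list alone. DESeq2 called 3 of 3 higher in group I, and in group II 4 higher and 1 lower. With library totals edgeR called none of group I, and in group II 0 higher and 3 lower.

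The miR-17-92 cluster and its paralogs, which promote proliferation, had a median score of 2.00 against 0.12, with 13 of 15 above the others' median (adjusted permutation p = 0.268). hsa-mir-106b scored 3.71 ± 1.00, hsa-mir-18a 3.25 ± 0.06, hsa-mir-93 3.17 ± 0.68 and hsa-mir-19b-1 3.12 ± 0.53, and these 4 were called higher. hsa-mir-17 at −0.93 ± 0.46 and hsa-mir-20a at −0.46 ± 0.18 (n = 2 each) were called lower by edgeR with Benjamini-Hochberg adjustment. With the replicate block, which models the pairing, 4 were called higher and 1 lower, so 1 of these calls was lost. Over the list alone the counts were 4 and 1, DESeq2 called 9 higher and 0 lower, and library totals gave 3 and 2. Blood-cell pri-miRNAs had a median of 2.52 (10 of 11 above the others' median) and the stem-cell clusters miR-302, miR-367 and miR-371-373 a median of 2.28 (8 of 8). Their adjusted permutation p were 0.200 and 0.268, and each passed only when means replaced medians (0.0310 and 0.0336, against 0.0835 to 0.275 and 0.193 to 0.520 under the other alternatives). The remaining lists did not pass. Their medians were 2.36 for the miR-23/24/27 clusters, 1.40 for the miR-34 and miR-449 family, 1.39 for muscle, 0.99 for miR-15/16, 0.98 for miR-30, 0.98 for neural, 0.96 for miR-200, 0.51 for the 14q32 imprinted cluster, 0.50 for miR-181 and −0.65 for miR-29, with adjusted permutation p from 0.268 to 0.884. Within small families the spread was wide: hsa-mir-200c, of the epithelial miR-200 family, scored 5.08 ± 0.67 and hsa-mir-200b 0.19 ± 0.18 (n = 2 each). As given below, the middle product of hsa-mir-200b that joined both flanks was a short one, of a class the score leaves out. The gap therefore does not show how much less hsa-mir-200b was cut in all.

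The 5′ ends of pre-miRNA-like products were somewhat more uniform than the 3′ ends. Over 1218 pri-miRNAs with at least 100 such reads in each technical replicate, 59.3% ± 23.1 (SD over pri-miRNAs) of reads shared the most used 5′ nucleotide and 56.4% ± 24.3 the most used 3′ nucleotide. The 5′ share was the higher in 762 pri-miRNAs and the 3′ share in 442. The difference of 2.96 points had a sign-flip permutation p of 1e-05 over pri-miRNAs, the smallest 100000 permutations can give. It was positive in each of the 5 replicates, at 2.73, 0.946, 14.8, 3.34 and 2.44 points, with an exact sign-flip p over replicates of 0.0625, the smallest that 5 replicates allow. With at least 1000 reads the difference was 1.08 points (sign-flip permutation p = 0.0036), and without replicate 1 it was 1.83 points (1e-05).

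hsa-mir-144, an erythroid pri-miRNA (chromosome 17, 28861533 to 28861618), was cut almost always at one nucleotide, with 98.8% ± 0.06 of reads at the main 5′ position. hsa-mir-1271 followed with 98.7% ± 0.44 (n = 2 each). The similar hsa-mir-513a-1 and hsa-mir-513a-2 both gave 98.6% ± 0.52 and hsa-mir-514a-3 98.5% ± 0.20 (n = 3 each), with 99.7%, 67.0% and 23.6% of reads at split values. The values of hsa-mir-514a-3 are also identical to those of hsa-mir-514a-2, so none of its reads can be told from those of the copy. The lowest shares were 9.36% (5.96 to 13.8) at hsa-mir-4255 and 10.3% (7.68 to 13.3) at hsa-mir-4319 (1 replicate each, with 95% Clopper-Pearson intervals in brackets here and for other shares from 1 replicate). Both were measured in replicate 5 alone. The identical hsa-mir-3687-1 and hsa-mir-3687-2 gave 12.6% (9.28 to 16.6) in replicate 1 alone. At hsa-mir-1302-3 the share was 12.1% (7.85 to 17.1) of 210 reads of 45 to 90 nt in replicate 5, with 58.2% of its reads at split values, but its main product was longer, 14 to 110 (97 nt), and 82.95% ± 5.03 of its 5′ flank reads ended at the main position (n = 3). The median 5′ share was 58.2%, 76.8%, 62.5%, 57.4% and 52.3% in replicates 1 to 5, so the order can depend on which replicates measured a pri-miRNA. hsa-mir-548h-3 and hsa-mir-152, in an intron of COPZ2, shared most of their reads between a pair of adjacent positions. The main 5′ position took 44.5% ± 0.34 and 55.4% ± 1.38 of their reads and the next 42.7% and 41.3% (n = 2 each), and the 2 positions exchanged rank between replicates. In replicate 1 alone, the second position held 44.4% (41.6 to 47.2) at hsa-mir-3189, 42.7% (41.0 to 44.4) at hsa-mir-6070 and 42.6% (37.8 to 47.4) at hsa-mir-1229.

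Members of the conserved families gave more uniform 5′ ends than the rest, with a median main-position share of 75.9% against 56.0% (172 members, adjusted permutation p = 1.9e-04, higher in 4 of 4 replicates with 3 or more members). Of this gap 5.15 points were expected from replicate membership alone and 14.7 lay beyond it. The late-numbered pri-miRNAs gave less uniform ends, 50.9% against 67.9% (589 members, adjusted permutation p = 1.9e-04, lower in 4 of 5 replicates). Of this gap −8.05 points were expected from replicate membership and −8.98 lay beyond it. Here too conserved members were not compared only with pri-miRNAs that were not late-numbered. The miR-17-92 list had a median of 89.9% against 58.1%, with 11 of 15 members above the others' median, and was higher in 2 of 2 replicates (adjusted permutation p = 0.0072; 25.7 points beyond replicate membership). hsa-mir-93, hsa-mir-92a-1 and hsa-mir-18a gave 95.7% ± 1.76, 95.6% ± 1.76 and 94.6% ± 1.22 (n = 2 each). This call was lost with means in place of medians (adjusted permutation p = 0.132) and without replicate 1 (0.0838), against 0.0051 to 0.0139 under the other alternatives. None of the other 16 lists passed with all replicates.

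Products cut on one arm only were mostly cut on the 5′ arm. They were the more frequent kind in 886 pri-miRNAs, against 325 with more products cut on the 3′ arm alone. The mean log2 ratio of 3′-arm-only to 5′-arm-only reads was −0.99, or 1.98-fold more of the 5′-arm-only kind (sign-flip permutation p = 1e-05 over 1218 pri-miRNAs, the smallest 100000 permutations can give). The ratio was −1.13, −1.09, −0.17, −0.85 and −0.86 in replicates 1 to 5, and its mean over replicates −0.82 ± 0.39 (exact sign-flip p = 0.0625, the smallest possible). In replicate 3 alone, with 37 pri-miRNAs, the sign-flip permutation p was 0.498. Taking only ends within 1 nt of the main site moved the ratio to −1.87. The median share of single-arm products among these and the pre-miRNA-like reads was 16.7%, with large differences between replicates, from 1.15% in replicate 3 to 29.2% in replicate 5.

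hsa-mir-10b, which lies in a HOXD3 intron (chromosome 2, 176150303 to 176150412), had the highest share of reads cut on the 5′ arm alone, 87.4% (86.1 to 88.5), followed by hsa-mir-7855 at 83.3% (82.0 to 84.5), hsa-mir-7703 at 78.4% (76.6 to 80.2), hsa-mir-17 at 76.5% (74.2 to 78.7) and hsa-mir-1287 at 75.8% (73.5 to 78.1). The highest shares cut on the 3′ arm alone were 76.8% (75.2 to 78.5) at hsa-mir-4680, 76.1% (74.7 to 77.5) at hsa-mir-1244-4, 71.3% (70.3 to 72.2) at hsa-mir-5691, 71.0% (69.5 to 72.4) at hsa-mir-3142 and 69.9% (68.4 to 71.5) at hsa-mir-8052. Each of these 10 was measured in replicate 1 or replicate 5 alone, where the median single-arm share was 18.4% and 29.2%, against 1.15% to 7.63% in the other replicates, so the order can depend on which replicate measured a pri-miRNA. hsa-mir-1244-4 and hsa-mir-3142 had 44.3% and 61.7% of their reads at values split between copies. hsa-mir-106a, a relative of hsa-mir-17, had 73.5% ± 21.5 cut on the 5′ arm alone (n = 2). Of 19 lists, the 14q32 imprinted cluster passed for the single-arm share, with a median 8.42 points above the others' 16.6%, or 13.1 points above the −4.67 expected from replicate membership (40 members, higher in 1 of 2 replicates, adjusted permutation p = 0.0201). Mirtrons, hairpins derived from small nucleolar RNAs and late-numbered pri-miRNAs had larger differences, 27.2, 27.8 and 12.1 points, of which 24.2, 25.3 and 12.5 were expected from replicate membership. Its mean was lower than that of the others by −1.40 points. The call ended with means (adjusted permutation p = 0.928) and without replicate 2 (0.819), against 0.0126 to 0.0437 under the other alternatives, and without replicate 1 the difference turned to −0.52 points (0.734).

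In 508 of 1286 pri-miRNAs (39.5%) the main middle product joined exactly onto the main 5′ flank and the main 3′ flank in 2 or more replicates, so that the same pair of cuts was read from 3 fragments. This count was chosen after the data were seen. In 395 of them the middle product was 45 to 90 nt long, with a median and mode of 60 nt, and 290 (73.4%) lay within 57 to 63 nt. Exact joining at both sides was seen in 36.2%, 52.02%, 27.7%, 39.7% and 34.7% of pri-miRNAs in replicates 1 to 5, against at most 4.82% in 100 shuffles of any replicate. The shuffles took flanks from other pri-miRNAs, whereas any break leaves ends that meet within a pri-miRNA. This contrast therefore cannot tell cuts by Microprocessor from other breaks. hsa-let-7a-1 was cut to positions 25 to 96 (72 nt), hsa-let-7a-2 to 28 to 94 (67 nt) and hsa-mir-98 to 22 to 100 (79 nt). hsa-mir-18a gave 28 to 92 (65 nt), hsa-mir-30a 30 to 92 (63 nt), hsa-mir-200c 30 to 91 (62 nt) and hsa-mir-144 33 to 90 (58 nt). These pairs rest on replicates 1 and 2: without replicate 1 the count of 395 was 48 and without replicate 2 it was 39.

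**Figure D3:**
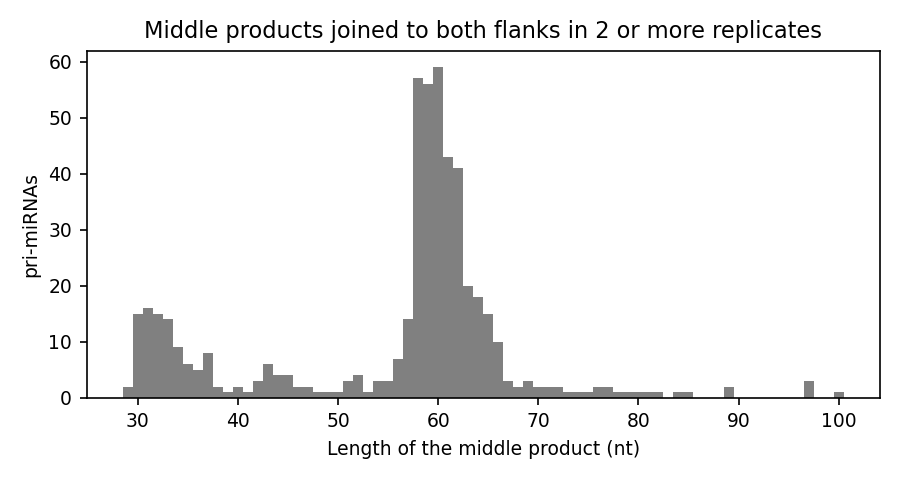
Number of pri-miRNAs (y axis) by length of the middle product in nt (x axis), for the 508 pri-miRNAs whose middle product joined both flanks in 2 or more replicates. The main peak lies at 60 nt and a smaller group of 109 between 28 and 44 nt.

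Another 109 pri-miRNAs were cut to a short middle product of 28 to 44 nt, with a median of 33 nt. Their number was 20 without replicate 1, 21 without replicate 2 and 53 with at least 500 flank reads. The median 5′ and 3′ flanks were 43 and 48 nt, against 30 and 35 nt for the longer products. hsa-mir-4720 was cut to positions 49 to 79 (31 nt), hsa-mir-181b-2 to 46 to 77 (32 nt), hsa-mir-200b to 44 to 77 (34 nt) and hsa-let-7c to 39 to 81 (43 nt). The median processing score, which counts only products of 45 to 90 nt, was −0.25 for pri-miRNAs with a short pair and 2.68 for those with a longer pair. A longer pair was found in 78.9% of neural members against 29.99% of the others (Fisher's exact test, adjusted p = 1.12e-04), 71.4% of miR-17-92 members (0.0073), 83.3% of miR-30 members (0.0341), 6 of 8 members of the stem-cell clusters (0.0341) and 56.9% of the chromosome 19 list (3.84e-04). It was found in 58.4% of conserved members against 26.4% (4.3e-15) and in 17.2% of late-numbered pri-miRNAs against 44.3% (3.65e-25). The conserved and late-numbered comparisons overlap and are not separate results. Short pairs were more frequent among late-numbered pri-miRNAs, 11.01% against 5.93% (Fisher's exact test, adjusted p = 0.0242).

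**Figure D4:**
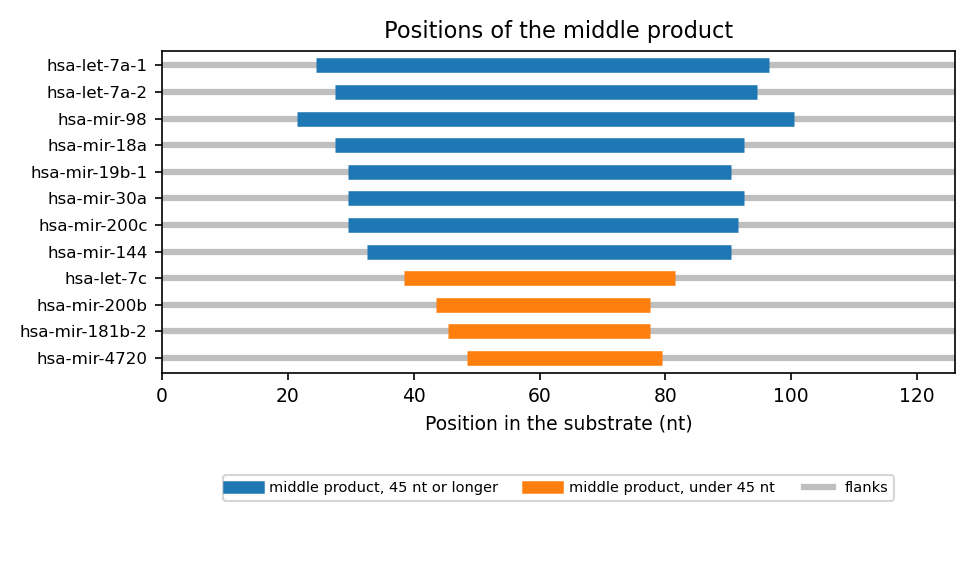
Positions of the middle product along the 125-nt substrate (x axis, nt from the 5′ end) for 12 named pri-miRNAs (y axis), with flanks in grey. Blue bars are products of 45 nt or longer, such as 25 to 96 in hsa-let-7a-1, and orange bars shorter ones, such as 49 to 79 in hsa-mir-4720.

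A UGU or GUG motif in the apical loop, a known recognition element for DGCR8, went with no detected difference in score. The 351 pri-miRNAs with the motif had a median of 0.16 and the 1470 without it 0.14 (permutation p = 0.986). Without replicate 2 the difference was −0.20 (permutation p = 0.308). The loop was taken from the predicted fold of the annotated hairpin. The basal UG and CNNC motifs were not tested, since the flanking sequence of the substrates is not given in the sources used here.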

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

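The tests over shared pri-miRNAs below were chosen after replicate 3 had been seen to stand apart, and before their own results were seen.

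In replicate 3 the 5′ ends were 14.8 points more uniform than the 3′ ends, against 0.946 to 3.34 points in the other 4 replicates. It was the 1 value among 13 measures compared between replicates that lay beyond Dixon's 95% limit for a single distant value, with a gap of 0.827 of the whole range, and chance alone passes that limit in about 1 in 20 measures. Replicate 3 also had the largest share of short middle products, 38.02% of reads. This share differed between technical replicates too, at 34.2% and 41.2% in replicate 3 and 18.9% and 33.0% in replicate 4. Reads in no class made up 11.4% and 7.35% of the product libraries of replicate 3, against 1.55% to 2.84% in the other replicates. A different composition of its substrate pool was tested as the explanation. Over the 35 pri-miRNAs measured in both replicates 3 and 4 the precision difference was 14.3 points larger in replicate 3 (34 of 35 pri-miRNAs, sign-flip permutation p = 1e-05, the smallest possible), and over the 86 shared with replicate 2 the short middle share was 7.11 points larger (72 of 86). For the short share these were means per pri-miRNA of 26.0% against 18.9%, a smaller gap than in all reads, 38.02% against 15.8%. Part of the gap in all reads may therefore go with composition or with the weighting by reads. The 2 differences over shared pri-miRNAs argue against composition as the whole cause. Other technical differences of replicate 3, whose product libraries were the smallest (444595 and 527789 reads), were not tested. All replicates share 1 design, so no biological explanation was tested.

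Product reads were also counted for the 57 pri-miRNAs left without a score because their input was too low. They had 363574 product reads, 0.765% of all, and 43 of them had 100 or more. hsa-mir-3150a had 65926 product reads with 0 input reads, hsa-mir-4776-1 57448 with 11, hsa-mir-625 42804 with 3, hsa-mir-3922 29325 with 14 and hsa-mir-5583-1 28802 with 15.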

How the results depend on the processing

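The fit on replicates 1 and 2, the splits of the samples, the cut-pair counts and the settings with identical copies kept once, replicates 1 and 2 only, other centring, a wider loop or no X-linked members were chosen after the data were seen. Of 888 alternative values, 786 kept their direction and side of the threshold or moved by less than the spread, 4 lost a call, 6 gained one, 60 moved and 32 changed sign; except where construction shows it, the cause was not tested. The score differences of the chromosome 19, late-numbered and conserved lists kept their direction and call under all alternatives run (1.37 to 3.60, −2.97 to −1.40 and 0.95 to 2.33; highest adjusted permutation p 0.0020, 0.0010 and 0.0047). The precision difference (1.08 to 3.32 points) and the single-arm ratio (−1.87 to −0.76) also did. List values here are differences beyond that from replicate membership. Depth limits replicates 2 and 3, with a median of 965 and 900 product reads per pri-miRNA.

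With the replicate block, which models the pairing of input and products, 136 pri-miRNAs were called in replicates 1, 2 and 5 in place of 18, 96 in replicates 2, 3 and 4 in place of 64, and 1061 in replicates 1 and 2 in place of 1036. In replicates 1, 2 and 5 the count was 87 with DESeq2, 57 with library totals, 0 with all fragments (edgeR, 22 at an unadjusted p under 0.05), 0 without a filter (19) and 0 to 131 without 1 replicate. In replicates 2, 3 and 4, with 19 higher and 45 lower, it was 34 with all fragments (17 higher, 17 lower), 20 without a filter (20 higher, 0 lower) and 0 to 90 without 1 replicate. Without a filter 1867 pri-miRNAs were tested in place of 193 and 1864 in place of 118, and none of the 20 was among the 64. Of the 10 splits of the 6 samples in each of these fits, 1, the real one, gave as many calls (18 and 64; highest other 0), and 10 splits are too few for a share under 0.05. The score's interquartile range moved to 2.86 with all fragments and 3.74 without an input minimum. With all fragments hsa-mir-1302-9 and hsa-mir-1302-11 scored 1.08 and hsa-mir-4720 1.13.

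With means in place of medians the score difference became a call for blood-cell (2.23) and stem-cell (2.53) lists, and the 5′ share of miR-17-92 (9.90 points) and the single-arm share of 14q32 (2.37) lost theirs. Means also turned the sign for miR-23/24/27 (5′ share 1.37, single-arm −1.79), and in single-arm share for the miR-34 and miR-449 family (4.13), muscle (−4.35), blood-cell (−1.73), chromosome 19 (−0.975) and late-numbered (0.642). With all fragments the miR-181 score difference was −0.52. With an input minimum of 100 the single-arm differences of blood-cell (−0.0854) and late-numbered (0.153) changed sign. The chromosome 19 list gained a 5′ share call in replicates 1 and 2 (13.7 points) and a single-arm call without X-linked members (5.10). With at least 500 flank reads 53 short pairs were left.

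Leaving out 1 replicate gave these ranges. Score differences were −0.10 to 1.79 for miR-15/16, −0.39 to 2.07 for neural and −0.20 to 0.11 for the apical motif. 5′ shares differed by 19.01 to 27.8 points for miR-17-92, −5.42 to 6.47 for miR-23/24/27, 15.3 to 32.5 for stem-cell, 7.21 to 15.4 for chromosome 19 and −6.39 to 3.55 for mirtrons. Single-arm shares differed by −0.402 to 9.42 for miR-17-92, −16.3 to 0.177 for miR-15/16, −8.68 to 3.67 for miR-23/24/27, −5.96 to 2.42 for muscle, −11.3 to 1.63 for blood-cell, −3.81 to 2.04 for neural, −3.51 to 7.66 for stem-cell, −0.523 to 13.8 for 14q32, −3.42 to 2.11 for chromosome 19, −0.557 to 9.24 for late-numbered and −1.27 to 2.46 for conserved. The late-numbered 9.24, without replicate 2, had an adjusted permutation p of 0.0019, against 0.734 to 0.981 in the named alternatives. Pairs of 45 to 90 nt numbered 39 to 393 and short pairs 20 to 108. Other positions of the basal motifs were not run, since the flanking sequence is not given in the sources used here.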

Other observations

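The test of joining for short middle products, and the counts of those with identical copies or with no split value, were chosen after the result was seen; the other tests below were written before their results were seen.

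Pri-miRNAs with a more stable predicted hairpin had higher scores, with Pearson's r of −0.52 and Spearman's rho of −0.52 between score and folding energy per nt over 1821 pri-miRNAs. This runs across pri-miRNAs, which are not independent replicates, and had no test. GC content had r −0.13 and the abundance in the input r −0.17. Input reads are the denominator of the score, so the relation with abundance may be partly built in. With the hairpins in 5 groups by folding energy, in the least stable group the median score was −2.88 for late-numbered and −1.99 for other pri-miRNAs, and in the most stable group 2.31 and 2.73. In the groups between these the gap was larger, at −1.85, −2.65 and −2.93 from more to less stable.

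The lower score of late-numbered pri-miRNAs, −2.16 against the others, was compared within 5 groups by each of 3 properties. The mean gap was −1.79 for GC content of the hairpin, −1.63 for its folding energy and −2.26 for the abundance of the substrate in the input. Membership was permuted within the groups to test the pooled difference of −2.16 (permutation p = 1e-04 each, the smallest possible). The mean gaps themselves had no test. Late-numbered hairpins were predicted slightly more stable (median −0.460 against −0.445 kcal/mol per nt), which goes with higher scores. The gap of −1.63 within groups argues against folding energy as the whole cause. The gap was −0.42 in the most stable and −0.89 in the least stable group, so its size varied with folding energy. These values do not settle whether part of the lower score goes with folding energy. The substrates of late-numbered pri-miRNAs were slightly less abundant (median input share 5.66e-04 against 5.91e-04). Lower abundance also goes with higher scores, a relation that may be partly built in. The gap of −2.26 within groups argues against abundance as the whole cause. GC content was higher (median 54.1% against 46.9%) and goes with lower scores, but the gap of −1.79 within groups argues against it as the whole cause. The gap was −0.16 in the group with the lowest GC content, so its size varied with GC content. Whether part of the lower score goes with GC content stays open. Replicates 3 and 4 did not show the lower score, and no biological explanation was tested, since the design holds 1 treatment.

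Short middle products of 28 to 44 nt could come from breakage at random positions or from reads shared between similar pri-miRNAs. Where the main middle product was short, it joined both main flanks in 17.4% of 812 pri-miRNAs in replicate 1, against at most 0.985% in 100 shuffles. In most of the 812 it did not join both. The shuffles took flanks from other pri-miRNAs, whereas any break leaves ends that meet within a pri-miRNA. The test therefore cannot exclude breakage. Over 10% of reads at split values were found in 9 of the 109 pri-miRNAs with a short pair (8.26%, 95% Clopper-Pearson interval 3.85 to 15.1). Bounds of 10% and 50% had been set for this share, which lay below 10%, though its interval reached above. With values identical to those of another pri-miRNA, added after the result was seen, the count was 12 of 109 (11.01%, interval 5.82 to 18.4). For these 12 shared reads stay open. In 89 of the 109 (81.7%, interval 73.1 to 88.4) no value was split and no copy identical, which argues against shared reads there. Whether a second cut by Microprocessor or another nuclease made the short products was not tested, as no reaction without enzyme was analysed here.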
